A study of Homo sapiens with 48 samples.

How the data were processed

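RNA of human endothelial cells, mesangial cells, and podocytes and intermediate mesoderm (IM) cells made from stem cells was sequenced as 3' tag libraries (QuantSeq, per the labels' protocols) from plates, the IM chip, the bi-culture chip (BGC) and the tri-culture chip (TGC), with 48 libraries in 12 groups of 4. Per the labels' protocols, endothelial cells were taken from the chip with TrypLE, mesangial cells were lysed in the bottom channel afterwards and podocytes were lysed in the top channel. The deposited table of counts holds whole read counts per gene as made by the authors, with the aligner and the role of each genome build not given in the sources used here; the submitters' processing notes list GRCm38, mm10 and GRCh38 with no role given. The deposited log2 table holds log2 of each count over 1 factor per library, plus 1, as checked from the deposited counts (largest relative deviation 3.6e-14, factors 0.777 to 1.373), and was used for that check alone. Of 19912 genes, 19902 have an identifier in GENCODE 29 and 19784 in the gene names table, and 121 had no symbol in the file; positions in the text are those of GENCODE 29 on GRCh38, since the files hold none. XIST, TSIX and the genes of the Y chromosome (45 genes) were left out of all steps, and 19867 genes were used. All 48 columns were matched to a sample.

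CPM are counts scaled to the library total, and library totals ran from 2674704 to 5504305 (median 3796163). Mitochondrial genes took 8.91% ± 1.3 of counts in the endothelial fraction of TGC and 5.42% ± 0.362 in endothelial plates, 8.87% ± 0.499 and 4.15% ± 0.137 in the podocyte fraction and plates, and 7.96% ± 0.217 and 6.09% ± 0.284 in the mesangial fraction and plates. The 10 most abundant genes took 15.5% and 7.48%, 14.3% and 8.17%, and 13.3% and 7.69% of counts in the same groups. Where the lower group had 0 counts over its 4 libraries, the fold is given as at least the ratio to a floor of 3 counts, and where it had 1 to 3 counts as the ratio of pooled counts with an exact 95% counting interval.

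Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, quasi-likelihood F test, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05), in a fit for each lineage: 16 endothelial libraries, 20 of podocytes and IM cells, and 12 mesangial libraries. There were 14 comparisons of 2 groups and 4 tests of a difference of changes between cell types, of which the one between TGC and BGC carried the number in the library names as a block, which the labels tie to a chip for the IM chip and not for TGC and BGC. The comparisons, the key genes, 26 gene lists and the rule for naming genes were fixed before the data were examined. The rule names, for main comparisons, the 6 largest rises and falls among genes past the threshold with no overlap between libraries and at least 10 CPM in the higher group, genes without a common name left out, the key genes of the cell type and 2 members of up to 6 lists with the smallest camera p, and for other comparisons 3 rises, 3 falls and the key genes. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and at an estimated correlation, and with fry, adjusted over the lists of a comparison with at least 3 tested members. The lists were podocyte, endothelial, mesangial and pericyte, and IM and nephron progenitor identity, pluripotency, basement membrane, interstitial matrix, cell cycle, flow response, inflammation, interferon response, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein and amino acid stress, p53 response, YAP and SRF targets, Notch pathway, glomerular ligands and receptors, epithelial, neuronal, muscle, and blood and immune markers, mitochondrially encoded genes, dissociation and immediate early genes, and metallothioneins; blood and immune markers were used by level alone, since the list is absent from the tests for want of 3 tested members. Marker levels are the mean log2(CPM + 1) of a list and were compared by exact permutation of 4 against 4 libraries. Sets of genes specific to the plates of each cell type (at least 50 CPM and 50 times the level in other plates), 4 comparisons between cell types within TGC and within plates, and the genes named in those were chosen after the data were seen.

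Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, fits of the 2 groups compared, a required 2-fold change, leaving out each library, leaving out genes higher in the plates of another cell type, the replicate number as a block, leaving out the IM chip group or genes higher in the podocyte fraction, thinning to equal totals, and taking out a trend with transcript length and GC content (spline with 5 degrees of freedom). Pairing of libraries by number was checked by the correlation of their residuals over genes of at least 10 CPM: in no pair of groups were all 4 correlations above 0.1, the highest lowest value being that of the endothelial and mesangial fractions of the IM chip (0.1 to 0.52), so the comparisons of 2 groups are reported without a block, and the difference between the TGC and BGC changes kept its planned block. The tests were checked on simulated counts, where 68 of 100 genes changed 2-fold and 87 of 100 changed 4-fold were found for endothelial TGC against BGC, 77 and 92 for podocyte TGC against BGC, and 46 and 88 for mesangial TGC against plate, with 14, 11 and 8 unchanged genes called. Levels, exact tests and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Some genes that the rule names are not reported here. Reads shared between similar genes could not be separated, since the table holds gene totals.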

Results

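The series holds 48 RNA libraries from human cells grown either alone on plates or together in a 2-channel microfluidic chip that models the kidney glomerulus, the filter in which endothelial cells, podocytes and mesangial cells lie side by side. Primary glomerular endothelial cells, primary mesangial cells, and intermediate mesoderm (IM) cells and podocytes made from a human induced pluripotent stem cell line were used. The libraries form 12 groups of 4. Endothelial cells came from plates, the IM chip, the bi-culture chip (BGC, endothelial cells and podocytes) and the tri-culture chip (TGC, endothelial cells, podocytes and mesangial cells). Podocytes came from plates, BGC and TGC, IM cells from plates and the IM chip, and mesangial cells from plates, the IM chip and TGC. Plates were taken on day 0, the IM chip on day 1, and TGC and BGC, which ran under flow, on day 12, so device, flow and day cannot be separated in any chip-to-plate comparison. The labels call all TGC and BGC libraries non-stretched. The total count per library ranged from 2674704 to 5504305, with a median of 3796163. Totals were larger in TGC than in BGC, with means of 4956742 and 3489368 for the endothelial fractions and 4842329 and 3405004 for the podocyte fractions. The floor of 3 counts corresponds to 0.151 to 0.246 CPM (the count scaled to the library total) over a group of 4 libraries. Levels below are CPM as mean ± SD over n = 4 libraries, and log2 fold changes carry their standard error. Intervals and floors cover counting error only. The labels do not say whether the 4 libraries of a group come from separate cultures or donors, so p-values measure the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 2.042 to 35.554 over 72 pairs).

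The first question was what each chip fraction held. Genes specific to the plate cultures of each cell type were collected after the values had been seen, with at least 50 CPM in the plates of that type and at least 50 times the level in the other plates. The 48 genes specific to endothelial plates stood at 2.31% ± 0.704 of their plate level in the endothelial fraction of TGC and at 2.29% ± 1.7 in that of BGC, where replicate 24 was at 4.84% and the others at 1.26% to 1.55%, against 68.3% ± 32.4 in the endothelial fraction of the IM chip (medians over genes, SD over n = 4 libraries). The 40 genes shared by the podocyte and IM plates stood at 41.8% ± 2.32 of the podocyte plate level in the endothelial fraction of TGC, 39.5% ± 2.8 in the mesangial fraction and 44.0% ± 1.76 in the podocyte fraction. The endothelial fraction of BGC held them at 40.1% and the podocyte fraction of BGC at 43.5%. In the IM chip they stood at 15.4% ± 10.4 in the endothelial fraction and 48.2% ± 9.42 in the mesangial fraction. The 16 genes specific to mesangial plates stood at 0.164% ± 0.192 in the mesangial fraction of TGC and 0.483% ± 0.317 in that of the IM chip. Endothelial-specific genes stood at 20.7% in the mesangial fraction of the IM chip, from 5.56% to 48.2% between libraries. The falls of the endothelial-specific set in TGC and BGC and of the mesangial-specific set in TGC and the IM chip each reached the smallest value an exact two-sided permutation test of 4 against 4 can give, p = 0.0286 (adjusted p = 0.0464 over 13 tests). The endothelial fraction of the IM chip did not differ from the plates by that exact test (p = 0.1429). In these tests against plates, the plate libraries had also served to choose the sets and to scale their levels. The plate arm was therefore set near its full level in advance. These p-values are not independent evidence for a fall or for its absence, and the levels given above are descriptive. The stem-lineage set was lower in the endothelial than in the podocyte fraction of BGC (exact p = 0.0286, adjusted p = 0.0464), and in TGC neither the endothelial nor the mesangial fraction passed against the podocyte fraction (exact p = 0.2 and 0.0857).

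**Figure D1:**
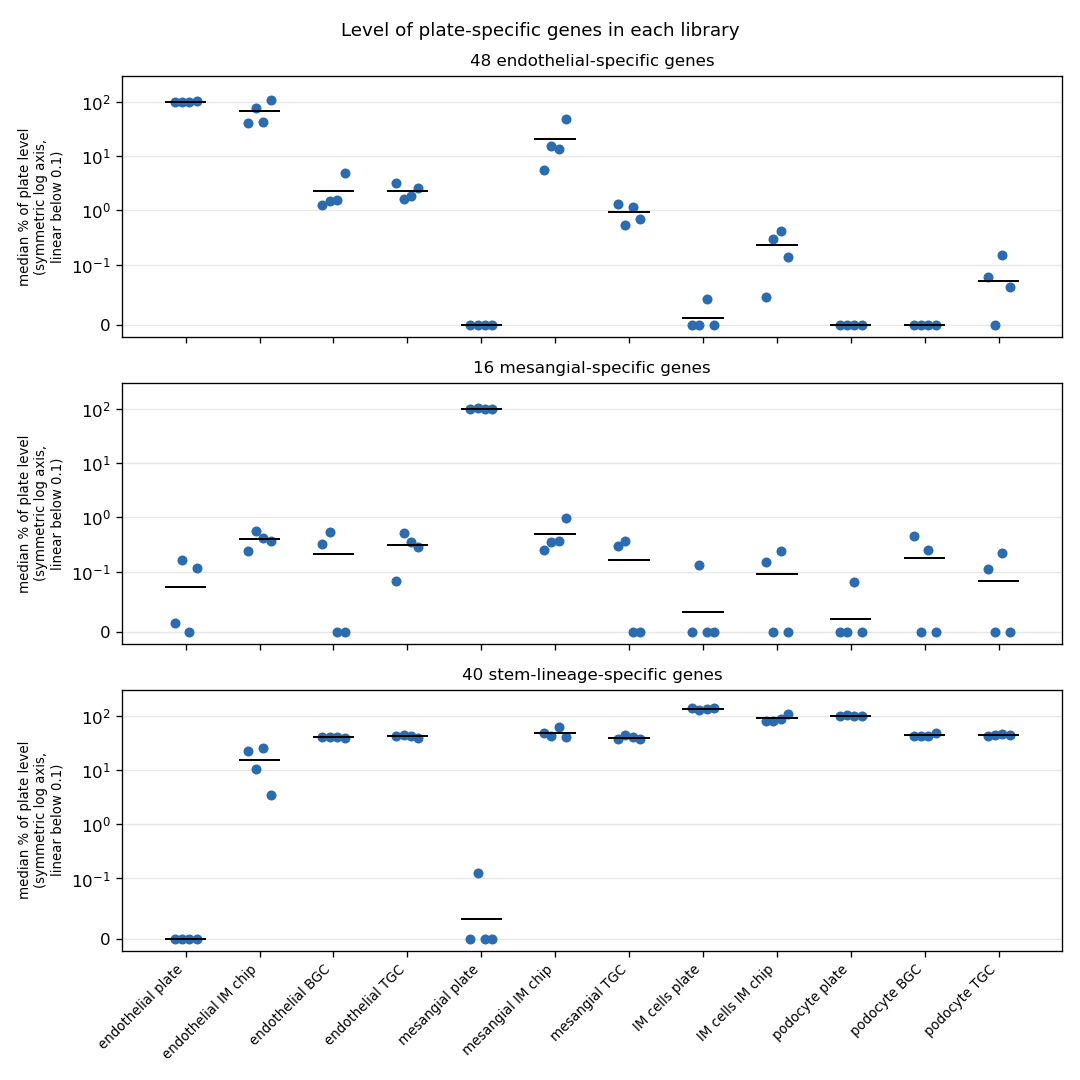
Median level of the 48 endothelial-specific, 16 mesangial-specific and 40 stem-lineage-specific genes in each library, in percent of the plate level, on an axis that is linear below 0.1 and logarithmic above; points are libraries and bars are group means. The means of the endothelial fractions of TGC and BGC are 2.31% and 2.29% in the upper panel, where 1 BGC library is at 4.84% and the others at 1.26% to 1.55%, and 41.8% and 40.1% in the lower panel.

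**Figure D2:**
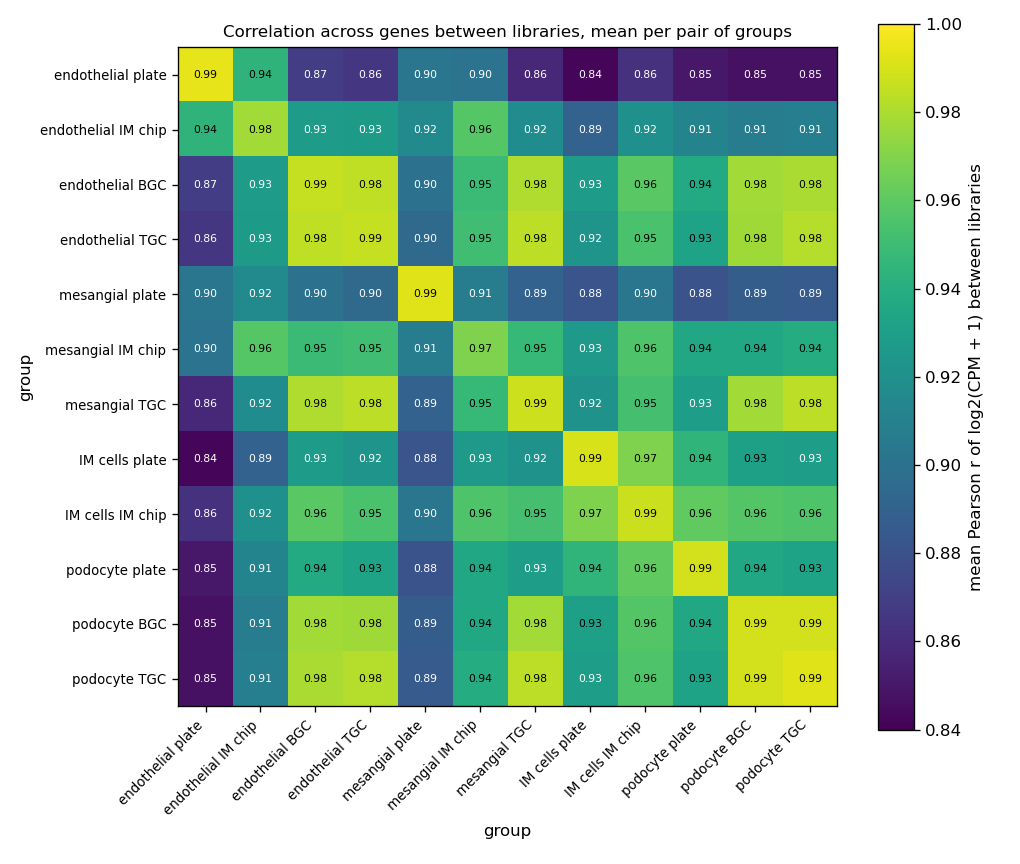
Mean Pearson correlation of log2(CPM + 1) between libraries for each pair of the 12 groups. Colours show the correlation, and rows and columns are groups ordered by cell type.

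The comparison of podocyte with IM plates addressed how differentiation of the stem cells into podocytes changed their expression. Cell cycle genes were lower in the podocyte plates: TOP2A (ENSG00000131747, chromosome 17, 40388516 to 40417950), the mitotic DNA topoisomerase, fell by 5.68 ± 0.16 on the log2 scale, from 806 ± 46.9 to 14.4 ± 4.99 CPM, and the proliferation marker MKI67 fell by 6.42 ± 0.23. KIF4A, a mitotic kinesin, was at least 157-fold lower. The p53 targets CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), an inhibitor of cyclin-dependent kinases, and MDM2, the ubiquitin ligase of p53, rose by 3.44 ± 0.11 and 2.57 ± 0.1. Of 17 tested podocyte identity genes 8 rose and 5 fell (camera adjusted p = 0.618; 9 rose adjusted over the list alone), and the mean log2(CPM + 1) of the list was 3.09 and 3.06 (exact permutation p = 0.5143). SYNPO (ENSG00000171992, chromosome 5, 150601080 to 150659220), an actin-binding protein of podocyte foot processes, rose by 2.52 ± 0.11 to 393 ± 41.8 CPM. PODXL (ENSG00000128567, chromosome 7, 131500262 to 131558217), the podocyte surface sialomucin, fell by 4.50 ± 0.15, from 1530 ± 61.3 to 62.2 ± 13.5 CPM. WT1 had 0 counts in both groups, PAX2 reached 0.0711 ± 0.142 CPM in the podocyte plates, and NPHS1, the gene of nephrin, was at 0.816 ± 0.433 CPM in the IM plates and 0 in the podocyte plates.

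Over the fixed gene lists, 28 of 29 cell cycle genes fell and 1 rose in the podocyte plates (camera adjusted p = 0.000184 with an estimated correlation), and all 15 genes of the p53 response rose (adjusted p = 1.76e-06 with an estimated correlation). Of 19 mesangial and pericyte genes, 13 rose and 4 fell (0.000395 with an estimated correlation), among them TAGLN and SERPINE2, which rose by 3.01 ± 0.1 and 3.48 ± 0.11. TAGLN also counts among the YAP and SRF targets, the genes that answer to actin tension, of which 13 of 15 rose and 1 fell (0.00425 with an estimated correlation), as did TPM1, by 2.20 ± 0.1. Cholesterol synthesis fell in 15 of 18 genes and rose in 2 (0.00251 with an estimated correlation), with LSS, lanosterol synthase, down by -1.88 ± 0.14. Of 18 genes of the unfolded protein and amino acid stress list, 11 rose, among them SESN2 (1.58 ± 0.11) and PPP1R15A (1.50 ± 0.15), with camera adjusted p = 0.0107 and adjusted p = 0.43 with an estimated correlation. Of 4 tested pluripotency genes 3 fell (camera adjusted p = 0.174). Adjusted over the list alone, the counts of these lists were the same. The muscle, endothelial, flow, hypoxia and glomerular ligand lists had a median, mean and test that differed in sign, and none of these passed. In all, 3269 genes were higher and 3325 lower in the podocyte plates of 11733 tested (edgeR quasi-likelihood test, adjusted p below 0.05). Markers of other cell types moved with the groups: the mean log2(CPM + 1) of mesangial and pericyte markers was 5.72 ± 0.06 in the podocyte plates and 4.80 ± 0.09 in the IM plates, and that of muscle markers 2.04 ± 0.09 and 2.45 ± 0.07, with epithelial markers higher and endothelial, IM and neuronal markers lower in the podocyte plates (each exact permutation p = 0.0286, adjusted p = 0.0421 over 112 tests).

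The comparison of the endothelial fraction of TGC with endothelial plates addressed how the cells differed after 12 days in the tri-culture chip. PECAM1 (ENSG00000261371, chromosome 17, 64319415 to 64413776), an adhesion molecule of endothelial junctions, fell by 4.52 ± 0.33 on the log2 scale, from 539 ± 12.5 to 20.6 ± 6.22 CPM, and CDH5 (ENSG00000179776, chromosome 16, 66366622 to 66404786), the gene of VE-cadherin, fell by 5.54 ± 0.37, from 326 ± 20.4 to 6.16 ± 1.49 CPM. VWF and NOS3, the endothelial nitric oxide synthase, fell by 2.72 ± 0.35 and 3.50 ± 0.23, and TIE1 and MMRN2 by 5.66 ± 0.37 and 4.56 ± 0.28. KDR, the main VEGF receptor, rose by 2.23 ± 0.19 to 181 ± 45.1 CPM, and EHD3, a glomerular endothelial marker, rose by 4.41 ± 0.44 to 20.6 ± 1.73 CPM. KDR stood at 290 ± 29.4 CPM in the podocyte fraction of TGC and at 67.4 ± 7.94 CPM in podocyte plates. The gene of collagen I, COL1A1 (ENSG00000108821, chromosome 17, 50183289 to 50201632), went from 0.889 ± 0.625 to 35600 ± 2220 CPM, a log2 change of 15.41 ± 0.74, and stood at 19000 ± 1560 CPM in the podocyte fraction. SPON2 (ENSG00000159674, chromosome 4, 1166932 to 1208962), a secreted matrix protein with 0 counts in the plates, was at least 12400-fold higher at 2200 ± 435 CPM, and the imprinted gene DLK1 rose by 13.71 ± 0.62 to 3180 ± 586 CPM, beside 2540 ± 286 and 3720 ± 356 CPM in the podocyte fraction. The water channel AQP1 was 13000-fold higher (95% counting interval 3600 to 107000). TCF15 and the retinoic acid receptor RARB were at least 132-fold and 124-fold lower, with 0 counts in TGC, and the cyclin CCNA1 fell by 8.57 ± 0.59.

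**Figure D3:**
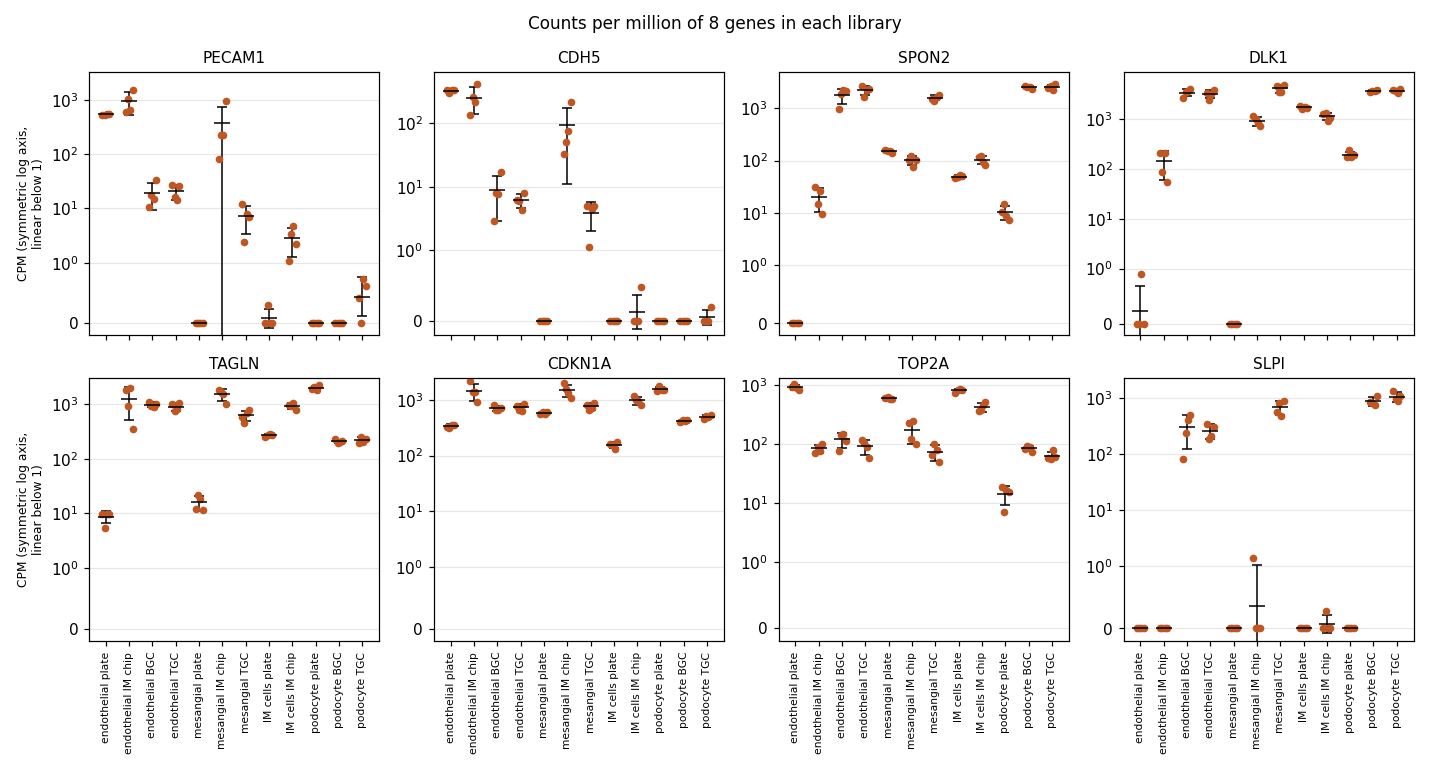
CPM in each library for 8 genes, on an axis that is linear below 1 and logarithmic above, for all 12 groups; points are libraries, and bars are means with SD. PECAM1 falls from a mean of 539 CPM in endothelial plates to 20.6 in the endothelial fraction of TGC, and SPON2 goes from 0 to 2200.

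All 29 cell cycle genes fell in TGC (camera adjusted p = 0.0295 with an estimated correlation), among them CCNB1, a mitotic cyclin, by -3.25 ± 0.17, and TYMS, thymidylate synthase, by -3.26 ± 0.16. Of 26 endothelial identity genes 21 fell and 4 rose (camera adjusted p = 4.95e-07, but adjusted p = 0.367 with an estimated correlation). Interstitial matrix genes rose in 17 of 24 and fell in 5 (3.74e-06, adjusted p = 0.367 with an estimated correlation), DCN 8890-fold (counting interval 1600 to 351000). Of 20 basement membrane genes 16 rose and 4 fell (0.000129, adjusted p = 0.367 with an estimated correlation), NID2 by 5.14 ± 0.27 and LAMA4 by -5.87 ± 0.34, and of 18 mesangial and pericyte genes 14 rose and 4 fell (0.000129, adjusted p = 0.367 with an estimated correlation), ACTA2 by 4.91 ± 0.26 and ITGA1 by 6.90 ± 0.37. The unfolded protein and amino acid stress list rose in 14 of 18 and fell in 2 (0.000101, adjusted p = 0.367 with an estimated correlation), PHGDH, an enzyme of serine synthesis, by 8.93 ± 0.67 and VLDLR by 5.36 ± 0.37. Adjusted over the list alone, the counts of these lists were the same. Stem-lineage-specific genes stood at 41.8% of podocyte plate level in the same libraries. The podocyte identity (7 rose, 8 fell of 18, and 9 fell adjusted over the list alone), flow response (5 rose, 4 fell of 11), hypoxia and glycolysis (7 rose, 8 fell of 19) and glomerular ligand lists (10 rose, 9 fell of 20) had a median, mean and test that differed in sign, and none passed (camera adjusted p = 0.658, 0.869, 0.61 and 0.869). In these libraries the mean log2(CPM + 1) of mesangial and pericyte markers was 5.32 ± 0.11 against 2.78 ± 0.02 in plates, of muscle markers 1.48 ± 0.12 against 0.33 ± 0.04, of epithelial markers 2.83 ± 0.08 against 2.06 ± 0.04 and of blood and immune markers 0.69 ± 0.13 against 1.12 ± 0.02, with IM markers higher and endothelial markers lower (each exact permutation p = 0.0286, adjusted p = 0.0421 over 112 tests). The mesangial and pericyte list does not mark mesangial cells alone here. It stood at 5.72 ± 0.06 in podocyte plates, 4.80 ± 0.09 in IM plates and 4.66 ± 0.02 in mesangial plates. In the endothelial fraction of BGC, a chip without mesangial cells, it stood at 5.29 ± 0.15. The 16 genes specific to mesangial plates stood at 0.31% ± 0.181 of plate level in the endothelial fraction of TGC. Over all genes, 4188 were higher and 3854 lower of 11830 tested.

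The endothelial fraction of BGC, the chip without mesangial cells, gave 3963 genes higher and 3756 lower than plates. COL1A1 rose by 15.03 ± 0.74 to 27700 ± 3130 CPM, SPON2 was at least 9860-fold higher, and PECAM1 and CDH5 fell by 4.65 ± 0.33 and 5.06 ± 0.36. KDR rose by 2.15 ± 0.19. BMX, a tyrosine kinase, was 1000-fold lower (counting interval 180 to 39600) and OAS3, of the interferon response, at least 75.4-fold lower. All 29 cell cycle genes fell (camera adjusted p = 0.0224 with an estimated correlation; the same count adjusted over the list alone). Mean levels of mesangial, IM, epithelial and muscle markers were higher, and of endothelial and blood and immune markers lower, than in plates (each exact permutation p = 0.0286, adjusted p = 0.0421). Endothelial identity fell in 20 of 26 genes (adjusted p = 0.319 with an estimated correlation).

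TGC and BGC were compared to ask whether seeding mesangial cells altered the other cell types. The 16 genes specific to mesangial plates stood at 0.164% ± 0.192 of plate level in the mesangial fraction of TGC. In BGC, without mesangial cells, they stood at 0.215% ± 0.262 in the endothelial and 0.176% ± 0.221 in the podocyte fraction. These genes therefore do not show that TGC held mesangial RNA on day 12, which limits what the comparison can say about mesangial cells. In the endothelial fraction no gene passed: edgeR's quasi-likelihood test called 0 of 11830 genes, with 1373 at an unadjusted p below 0.05, while DESeq2 called 130 (28 higher, 102 lower) and edgeR fitted on these 2 groups alone called 25. KDR differed by 0.08 ± 0.17, PECAM1 by 0.13 ± 0.32, CDH5 by -0.48 ± 0.4 and EHD3 by -0.05 ± 0.31, none past the test. PLVAP, the diaphragm protein of fenestrae, was at 0.305 ± 0.122 and 0.0785 ± 0.157 CPM, 4.22-fold with a counting interval of 0.512 to 194. No gene list passed; the smallest camera adjusted p was 0.213, for the basement membrane, of which 1 gene rose adjusted over the list alone, and no marker level passed the exact permutation test (smallest p = 0.0571). On simulated counts of this comparison the test found 68 of 100 genes changed 2-fold and 87 of 100 changed 4-fold. Those changes were set at the level of the whole fraction. Endothelial-specific genes stood at 2.31% and 2.29% of plate level in the fractions of TGC and BGC. The simulation therefore does not show what would be found for a change in endothelial cells alone.

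In the podocyte fraction, TGC and BGC differed at 420 of 11733 genes, of which 34 were higher and 386 lower in TGC. Of 35 splits of these 8 libraries, the real one included, 2 passed as many genes as the real groups did in a fit of these libraries (538), and the highest other passed 1234. Changes were small: 34 of the 420 were past 2-fold. BSG (ENSG00000172270, chromosome 19, 571277 to 583493), the cell surface glycoprotein basigin, rose by 0.64 ± 0.12, from 207 ± 28.4 to 320 ± 50.4 CPM, and the purine synthesis enzyme PFAS rose by 0.93 ± 0.26. EPHA2, an ephrin receptor, rose by 0.76 ± 0.21, MLST8, a subunit of mTOR complexes, by 0.73 ± 0.21, and MGME1, a mitochondrial exonuclease, by 0.80 ± 0.24. The centrosomal gene CEP112 fell by 1.17 ± 0.2 and the myosin MYO18A by 1.08 ± 0.24, and FLT1, a VEGF receptor, fell by 0.30 ± 0.09, from 1180 ± 70.7 to 951 ± 58.4 CPM. MT-ATP8 fell by 1.31 ± 0.17, ALG11 by 1.50 ± 0.25 and H4C3 by 1.57 ± 0.26; these 3 overlap or resemble other genes (MT-ATP6, a neighbouring gene and other histone H4 genes), so that their reads may be shared and their values are uncertain. PODXL, SYNPO and OSR1 differed by -0.02 ± 0.13, -0.11 ± 0.12 and -0.43 ± 0.41 and did not pass. No list passed camera (smallest adjusted p = 0.106, for oxidative phosphorylation), and of 8 marker lists the mean level of IM markers was higher in TGC (exact permutation p = 0.0286, adjusted p = 0.0421) and no other passed. DESeq2 called 547 genes, 52 higher and 495 lower, and leaving out single libraries moved the count of 420 between 193 and 733. The adjusted p of PFAS, MGME1, EPHA2, MLST8, RBM43 and FLT1 crossed 0.05 without some of the libraries. TGC libraries were deeper than BGC libraries, as given above.

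The podocyte fraction of TGC was compared with podocyte plates to ask how podocytes from the chip and from plates differed. The chip on day 1 held IM cells, so podocyte plates need not be the starting point of this fraction. The differences therefore do not show what 12 days in the chip changed. SLPI (ENSG00000124107, chromosome 20, 45252239 to 45254564), a secreted protease inhibitor, had 0 counts in the plates and stood at 1050 ± 203 CPM in TGC, at least 4830-fold higher. SAA1 (ENSG00000173432, chromosome 11, 18266174 to 18269977), an acute-phase protein whose reads may be shared with SAA2, was at least 2660-fold higher at 580 ± 58.1 CPM. PNMT, the enzyme that makes adrenaline, was 2850-fold higher (counting interval 789 to 23600). PODXL rose by 1.92 ± 0.14 to 208 ± 9.43 CPM, while SYNPO fell by 3.14 ± 0.11 to 39.5 ± 4.78 CPM. The natriuretic peptide NPPB was 1740-fold lower (312 to 69000), RGS5, a pericyte regulator of G protein signalling, fell by 7.15 ± 0.16 and CRHBP by 7.84 ± 0.26. WT1 was at 0 counts in both groups, PAX2 at 0 in TGC and NPHS1 at 0.241 ± 0.483 CPM in TGC and 0 in plates.

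Cholesterol synthesis rose in 16 of 18 genes in the podocyte fraction (camera adjusted p = 7.48e-05 with an estimated correlation), MSMO1 by 2.22 ± 0.11. The p53 response fell in 12 of 15 genes and rose in 1 (0.00309 with an estimated correlation; 13 fell adjusted over the list alone), MDM2 by -2.33 ± 0.1 and the stress cytokine GDF15 by -3.00 ± 0.19. All 3 tested metallothioneins rose (0.0192 with an estimated correlation), MT2A by 4.96 ± 0.16 and MT1E by 4.13 ± 0.18, with reads that these similar genes may share. Mesangial and pericyte genes fell in 13 of 19 and rose in 6 (0.00665 with an estimated correlation), CNN1, smooth muscle calponin, by -3.74 ± 0.13. The cell cycle list rose in 21 of 29 genes and fell in 2 (camera adjusted p = 0.00318, adjusted p = 0.263 with an estimated correlation), TOP2A by 2.30 ± 0.16 and HMGB2 by 2.51 ± 0.16. Against IM cells on the IM chip this list fell, as given below. Mitochondrially encoded genes rose in 11 of 13 and fell in 2 (1.86e-05, adjusted p = 0.0756 with an estimated correlation), MT-ND3 by 2.08 ± 0.09 and MT-ATP6 by 1.86 ± 0.1. The interferon response rose in 4 of 5 tested genes (0.0322, adjusted p = 0.117 with an estimated correlation), neuronal markers fell in 4 of 6 and rose in 2 (0.0246, adjusted p = 0.0756 with an estimated correlation), and the Notch pathway fell in 5 of 9 and rose in 1 (0.0361, adjusted p = 0.0756 with an estimated correlation). Dissociation and immediate early genes rose in 7 of 16 and fell in 6 (camera adjusted p = 0.742), and oxidative phosphorylation rose in 16 of 28 and fell in 1 (0.111). Where not given otherwise, the counts adjusted over the list alone were the same. The glomerular ligand list differed in sign between median and test and did not pass (camera adjusted p = 0.522). In total 3858 genes were higher and 3511 lower of 11733 tested. The mean log2(CPM + 1) of endothelial markers was 1.56 ± 0.07 in TGC and 1.16 ± 0.03 in plates, and that of blood and immune markers 0.45 ± 0.02 and 0.26 ± 0.07, while mesangial markers (4.67 ± 0.06 and 5.72 ± 0.06), epithelial markers (2.53 ± 0.08 and 3.01 ± 0.13), neuronal markers (0.52 ± 0.06 and 1.42 ± 0.03), muscle markers (1.55 ± 0.04 and 2.04 ± 0.09), podocyte markers (2.85 ± 0.08 and 3.09 ± 0.05) and IM markers (1.46 ± 0.04 and 1.72 ± 0.13) were lower in TGC (each exact permutation p = 0.0286, adjusted p = 0.0421), and endothelial-specific genes stood at 0.0728% of endothelial plate level.

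The podocyte fraction of BGC gave 3558 genes higher and 3313 lower than plates. SLPI and SAA1 were at least 3950-fold and 2820-fold higher, PODXL rose by 1.94 ± 0.14, and SYNPO fell by 3.03 ± 0.12. KRT7, a simple-epithelium keratin, was 729-fold lower (counting interval 130 to 28800). Cholesterol synthesis rose in 17 of 18 genes (9.2e-05 with an estimated correlation) and the p53 response fell in 13 of 15 and rose in 1 (0.00109 with an estimated correlation), with the same counts adjusted over the list alone. Mean levels of endothelial and of blood and immune markers were higher, and of the other 6 marker lists lower, than in plates (each exact permutation p = 0.0286, adjusted p = 0.0421).

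IM cells on the IM chip were compared with IM plates as the day-1 start of the chip culture. PODXL fell by 3.17 ± 0.14, from 1530 ± 61.3 to 156 ± 55.1 CPM, and SYNPO rose by 0.71 ± 0.11. ANGPTL7, a secreted angiopoietin-like protein, was at least 122-fold higher, C11orf87 fell by 6.61 ± 0.37 and the creatine synthesis enzyme GATM by 5.82 ± 0.42. The p53 response rose in 14 of 15 genes (camera adjusted p = 0.000135 with an estimated correlation), the interstitial matrix list in 18 of 24 with 4 lower (0.00221 with an estimated correlation) and cholesterol synthesis in 15 of 18 (6.92e-05 with an estimated correlation; 16 adjusted over the list alone). Mean levels of endothelial and mesangial markers were higher, and of neuronal and muscle markers lower, than in plates (each exact permutation p = 0.0286, adjusted p = 0.0421). In total 2607 genes were higher and 2363 lower. Between the podocyte fraction of TGC and IM cells on the IM chip, SLPI was 16300-fold higher in TGC (counting interval 2930 to 645000), SCGN, a calcium-binding protein, at least 263-fold higher, PODXL rose by 0.58 ± 0.13, while SYNPO fell by 1.32 ± 0.11 and APLNR, the apelin receptor, by 5.43 ± 0.48. Mean levels of blood and immune markers were higher, and of podocyte, mesangial, IM, neuronal and muscle markers lower, in TGC (each exact permutation p = 0.0286, adjusted p = 0.0421). Cell cycle genes fell in 28 of 29 (0.0124 with an estimated correlation; the same count adjusted over the list alone), and 3170 genes were higher and 3083 lower.

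The endothelial fraction of the IM chip, compared with plates, addressed the same cells after 1 day in the chip. PECAM1 rose by 0.84 ± 0.28 to 953 ± 424 CPM, VWF by 2.20 ± 0.3 and EHD3 by 4.08 ± 0.44, and CDH5 differed by -0.33 ± 0.28 (adjusted p = 0.34). Without IM chip replicate 4 the change of PECAM1 was 0.52 and no longer passed, and that of CDH5 was -0.66 and passed. NOS3 fell by 1.48 ± 0.21. COL1A1 rose by 13.19 ± 0.71 to 8510 ± 6180 CPM and COL6A3 was at least 1370-fold higher. All 29 cell cycle genes fell (camera adjusted p = 4.48e-05 with an estimated correlation; the same count adjusted over the list alone). By mean level, podocyte, mesangial, IM, epithelial, neuronal and muscle markers were higher than in plates (each exact permutation p = 0.0286, adjusted p = 0.0421). Inflammation genes rose in 12 of 13 (0.000341, adjusted p = 0.0869 with an estimated correlation). Stem-lineage-specific genes stood at 15.4% of podocyte plate level in these libraries, from 3.43% to 25.8%. In total 3177 genes were higher and 2373 lower. Against the IM chip, the endothelial fraction of TGC had PECAM1, CDH5 and VWF lower by -5.35 ± 0.34, -5.21 ± 0.36 and -4.92 ± 0.36, KDR higher by 1.24 ± 0.18 and SLPI at least 1260-fold higher. SPRR2F, of a gene family with shared sequence, was at least 161-fold higher. Endothelial identity fell in 20 of 26 genes and rose in 2 (5.68e-15, adjusted p = 0.109 with an estimated correlation) and inflammation fell in 10 of 13 and rose in 2 (2.56e-05, adjusted p = 0.109 with an estimated correlation), with the same counts adjusted over the list alone, and 2838 genes were higher and 2797 lower. Mean levels of podocyte, endothelial, neuronal, and blood and immune markers were lower in TGC than in the IM chip (each exact permutation p = 0.0286, adjusted p = 0.0421).

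The mesangial fraction of TGC was compared with mesangial plates to ask what 12 days in the chip changed in mesangial cells. The T-box factor TBX5 (ENSG00000089225, chromosome 12, 114353931 to 114408442) and SIM1 were at least 621-fold and 431-fold lower. TWIST2, a basic helix-loop-helix factor of mesenchyme, was 5490-fold lower (counting interval 984 to 217000). DLK1 (ENSG00000185559, chromosome 14, 100725705 to 100738224) was at least 21100-fold higher at 4130 ± 729 CPM, SLPI at least 3470-fold, KDR at least 1050-fold and the proteoglycan GPC3 at least 1020-fold; the podocyte fraction of TGC held DLK1 at 3720 ± 356, SLPI at 1050 ± 203 and KDR at 290 ± 29.4 CPM. PDGFRB (ENSG00000113721, chromosome 5, 150113837 to 150155872), the receptor that recruits mesangial cells, fell by 1.06 ± 0.14, from 168 ± 12.4 to 66.0 ± 7.89 CPM, beside 70.1 ± 5 CPM in the podocyte fraction. TAGLN (ENSG00000149591, chromosome 11, 117199321 to 117204782) and ACTA2, contractile proteins, rose by 5.57 ± 0.27 and 1.28 ± 0.17 to 628 ± 137 and 212 ± 28.5 CPM. DES, desmin, was 8.20-fold higher with a counting interval of 1.99 to 72.3, ITGA8 stood at 3.14 ± 1.44 and 0.921 ± 0.338 CPM, and GATA3 differed by 0.94 ± 0.91 (adjusted p = 0.39).

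Epithelial and tubular markers rose in 8 of 10 tested genes in the mesangial fraction of TGC (camera adjusted p = 0.0182 with an estimated correlation), AQP1 by 7.93 ± 0.25 and KRT18 by 4.07 ± 0.17. Of the unfolded protein and amino acid stress list 16 of 18 rose and 1 fell (3.6e-06, adjusted p = 0.0859 with an estimated correlation; 17 rose adjusted over the list alone), HERPUD1 by 2.43 ± 0.13 and ATF3 by 5.14 ± 0.29. Cell cycle genes fell in 24 of 29 (1.06e-05, adjusted p = 0.256 with an estimated correlation; 2 rose adjusted over the list alone), CENPF by -3.25 ± 0.26 and MKI67 by -2.71 ± 0.21. Interstitial matrix genes rose in 14 of 24 and fell in 9 (7.25e-05, adjusted p = 0.198 with an estimated correlation), TGFB2 by 7.98 ± 0.29 and COL6A3 by -5.25 ± 0.19. Basement membrane genes rose in 12 of 20 and fell in 2 (2.44e-05, adjusted p = 0.0994 with an estimated correlation), COL15A1 by 6.49 ± 0.21, and NPNT was 6550-fold higher (1170 to 259000). The intermediate mesoderm and nephron progenitor list fell in 6 of 10 and rose in 1 (0.000775, adjusted p = 0.101 with an estimated correlation; 7 fell adjusted over the list alone), GATA2 by -5.54 ± 0.49. Muscle markers rose in 5 of 6 tested genes and fell in 1 (0.00569, adjusted p = 0.101 with an estimated correlation), and the mean log2(CPM + 1) of that list was 1.63 ± 0.12 in TGC and 0.50 ± 0.06 in plates, with endothelial markers at 2.23 ± 0.37 and 1.23 ± 0.08, mesangial and epithelial markers also higher and IM, neuronal, and blood and immune markers lower in TGC (each exact permutation p = 0.0286, adjusted p = 0.0421). Stem-lineage-specific genes stood at 39.5% and endothelial-specific genes at 0.926% of their plate levels. The podocyte identity and hypoxia lists differed in sign between median and mean and did not pass. Where not given otherwise, counts adjusted over the list alone were the same, and 3572 genes were higher and 3499 lower of 11850 tested.

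The mesangial fraction of the IM chip, 1 day after seeding, had 3321 genes higher and 2982 lower than plates. DLK1 was at least 4700-fold higher, and the endothelial genes PECAM1 and MMRN1 at least 1800-fold and 1560-fold, at 368 ± 386 and 315 ± 201 CPM; PECAM1 was at 938 CPM in replicate 4 and at 82.0 to 227 in the others, so that its mean and bound rest largely on 1 library. PTN, a secreted growth factor, was at least 541-fold lower and PDGFRB fell by 1.19 ± 0.14, while TAGLN rose by 6.74 ± 0.28 and GATA3 by 5.89 ± 0.65. Endothelial identity rose in 21 of 23 genes and fell in 1 (camera adjusted p = 1.41e-10, adjusted p = 0.119 with an estimated correlation), metallothioneins fell in 4 of 4 (0.00875 with an estimated correlation), and epithelial markers rose in 8 of 10 (0.0034 with an estimated correlation), with the same counts adjusted over the list alone. The mean log2(CPM + 1) of endothelial markers was 4.84 ± 1.01 in this fraction against 1.23 ± 0.08 in plates, with podocyte, mesangial, epithelial and muscle markers also higher and IM and neuronal markers lower (each exact permutation p = 0.0286, adjusted p = 0.0421). Against the IM chip, the mesangial fraction of TGC had 1992 genes higher and 2146 lower. TAGLN fell by 1.16 ± 0.21, GATA3 by 4.94 ± 0.59 and BMX was at least 109-fold lower, while SLPI rose by 10.82 ± 0.47 and ITLN1, an intelectin, and the keratin KRT6A, which shares sequence with other keratins, were at least 171-fold and 134-fold higher. PDGFRB and ACTA2 differed by 0.14 ± 0.15 and 0.42 ± 0.16 (adjusted p = 0.5 and 0.051). Endothelial identity fell in 19 of 23 genes and rose in 2 (3.8e-07, adjusted p = 0.213 with an estimated correlation; 20 fell adjusted over the list alone). All 8 marker lists had a lower mean level in TGC, and all but that of IM passed (each exact permutation p = 0.0286, adjusted p = 0.0421). The IM list stood at 1.44 in TGC and 1.76 in the IM chip (exact permutation p = 0.1143).

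Whether cell types differed in their response was tested as a difference of changes. The TGC to BGC change did not differ between podocyte and endothelial fractions at any of 11365 genes by edgeR's quasi-likelihood test with the number in the library names, shared between fractions, as a block (466 at an unadjusted p below 0.05; 0 by DESeq2, with 300 unadjusted), and no list passed. The TGC to plate change differed between the podocyte and endothelial fractions at 7225 of 12055 genes, between the mesangial and endothelial fractions at 6364 of 12153 and between the mesangial and podocyte fractions at 6707 of 12055. For cell cycle genes the difference of change, podocyte minus endothelial, passed at 28 of 29 genes. It lay largely in the plates, where all 29 were higher in endothelial cells than in podocytes (median log2 difference 4.81). Between the endothelial and podocyte fractions of TGC the median was 0.40, with 3 higher and 1 lower of 28. KDR rose more in the mesangial fraction (at least 1050-fold, from 0 counts) than in the endothelial fraction (2.23 ± 0.19, from 43.8 ± 3.47 CPM). In TGC these fractions held KDR at 208 ± 20.5 and 181 ± 45.1 CPM. ACTA2 rose less in the mesangial than in the endothelial fraction (difference -3.58 ± 0.22). This too lay largely in the plates, where mesangial and endothelial cells held ACTA2 at 107 ± 10.8 and 10.7 ± 0.884 CPM. In TGC their fractions held it at 212 ± 28.5 and 282 ± 70.7 CPM. The difference in cell cycle change held as a list (adjusted p = 6.65e-07 with an estimated correlation).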

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

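All tests in this part were chosen after the results they test were seen, except the tests of the difference between cell types and the correction for transcript length and GC content, whose bound was written before its count was seen. The bounds that decide each test were set by hand after other values of the same pattern were known.

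In 426 groups of 4 libraries the highest or lowest library was compared with the rest by Dixon's ratio and its 95% critical value, over library measures, marker levels, plate-specific sets and the genes named in the text. The ratio passed in 30 groups, where chance alone would pass 21, about 1 in 20, so most of the values below may be chance, and the groups share libraries. In the mesangial fraction of the IM chip, replicate 4 stood apart with 12440 genes with a count (others 13238 to 13370), neuronal markers at 0.837 (1.17 to 1.2), mesangial-specific genes at 0.952% of plate level (0.255 to 0.373), GATA3 at 37.8 CPM (11.0 to 15.1) and PECAM1 at 938 CPM (82.0 to 227), and replicate 3 with 11.9% ribosomal protein counts (16.9 to 17.9). In the endothelial fraction of BGC, replicate 21 had 13.2% ribosomal protein counts, KDR at 112 CPM and COL1A1 at 23100 CPM, and replicate 24 had endothelial-specific genes at 4.84% of plate level (1.26 to 1.55). Endothelial plate replicate 2 had 10.3% ribosomal protein counts, CDH5 at 296 CPM, PLVAP at 2.29 CPM and TAGLN at 5.49 CPM, and replicate 3 had KDR at 48.9 CPM. In the podocyte fraction of TGC, replicate 11 had MT-ATP8 at 1810 CPM (737 to 897), and replicate 12 had OSR1 at 5.72 CPM and SPRR2F at 142 CPM. In that of BGC, replicate 23 had endothelial markers at 1.65 and replicate 24 stem-lineage-specific genes at 47.0%. Podocyte plate replicate 4 had 4.35% mitochondrial counts and ACTA2 at 141 CPM, replicate 2 stem-lineage-specific genes at 105% and replicate 3 NPPB at 101 CPM. IM plate replicate 1 had TOP2A at 737 CPM and MKI67 at 176 CPM, replicate 2 blood and immune markers at 0.102 and replicate 4 PPP1R15A at 33.3 CPM. Mesangial TGC replicate 12 had podocyte markers at 2.63, and IM cells on IM chip replicate 4 had APLNR at 23.9 CPM. The endothelial RNA in the mesangial fraction of the IM chip is weighed below over group means, where 48 of the 48 endothelial-specific genes (100%) lay within 2-fold of their median share. Why replicate 4 stood apart from the other libraries was not tested.

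The change from plate to TGC differed between cell types by tests of the difference itself, at 7225 genes for podocyte minus endothelial, 6364 for mesangial minus endothelial and 6707 for mesangial minus podocyte. For podocyte minus endothelial, lists past the threshold with an estimated correlation were cell cycle (adjusted p = 6.65e-07), mesangial and pericyte identity (4.89e-05), interstitial matrix (0.000129), metallothioneins (0.00108), unfolded protein stress, the p53 response and epithelial markers (each 0.0192) and YAP and SRF targets (0.0489). For mesangial minus endothelial they were mesangial identity and interstitial matrix (each 0.00125), and endothelial identity and cell cycle (each 0.00892), and among genes KDR (adjusted p = 2.8e-14), ACTA2 (3.7e-13) and AQP1 (5.2e-08). For mesangial minus podocyte they were epithelial markers (0.000457), cholesterol synthesis and metallothioneins (each 0.000971), cell cycle (0.00162), the p53 response (0.0145), YAP and SRF targets (0.0163), unfolded protein stress (0.0182), mesangial identity (0.0209), and interstitial matrix, muscle markers and glomerular ligands (each 0.0394). All 3 counts include the plate levels, which differ between cell types. Of 50 splits per test, the real one included, no other passed as many genes, and the highest others passed 4254, 4962 and 3756. The splits shuffled cell type and plate or chip together. They therefore do not test the difference of changes by itself, and no conclusion on chance is drawn from them.

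The first pattern weighed is the fall of the endothelial-specific and mesangial-specific genes, with a rise of the stem-lineage-specific genes, in the endothelial and mesangial fractions of TGC. A few genes taking most of the counts are argued against by the shares themselves. The 10 most abundant genes took 15.5% of counts in the endothelial fraction of TGC and 7.48% in endothelial plates. Without them the endothelial-specific genes stood at 2.67% of plate level, a test that such shares had fixed in advance. A change of expression in the endothelial cells themselves cannot be told apart from a lower share of these cells, since the upper over the lower quartile of the remaining level was 2.39, between the bounds of 1.3 and 4 set for the 2 cases. RNA of stem-lineage cells would bring other abundant transcripts of the podocyte fraction along, which was tested on genes outside the stem-lineage-specific set with at least 50 CPM there and under 1 CPM in the plates of the cell type, in place of an earlier test that restated the pattern. In the mesangial fraction 80% of these genes (52 of 65) lay within 2-fold of the podocyte fraction, just at the bound for what such RNA needs, with 12 lower and 1 higher and ratios of 0.295 to 3.11. In the endothelial fraction 76.7% (102 of 133) did, with 29 lower and 2 higher and ratios of 0.0608 to 4.43, short of that bound, so that such RNA cannot be told apart there from a change in the cells themselves. The median ratio was 0.737 there and 0.646 in the mesangial fraction, so the hand-set bound does not show that the 2 fractions differ in this. Endothelial libraries of TGC correlated at a mean of 0.982 with the podocyte fraction of TGC and at 0.865 with endothelial plates, whatever the cause. TAGLN, ACTA2 and COL1A1 stood above the podocyte fraction in the endothelial fraction, by 2.00 ± 0.14, 1.61 ± 0.16 and 0.89 ± 0.13, though endothelial plates held 8.75, 10.7 and 0.889 CPM, and TAGLN and ACTA2 in the mesangial fraction, by 1.53 ± 0.14 and 1.25 ± 0.12, though mesangial plates held 16 and 107 CPM. RNA with the profile of the podocyte fraction alone would give neither. Podocyte plates, also of the stem lineage, held TAGLN, ACTA2 and COL1A1 at 2000 ± 172, 139 ± 0.855 and 15600 ± 2770 CPM. Whether stem-lineage cells with another profile than the podocyte fraction gave these levels was not tested. Cells crossing between the channels, carry-over of lysate and loss of the primary cells over 12 days could each bring such RNA, and none of these was tested. In the IM chip on day 1, the mesangial fraction already held mesangial-specific genes at 0.483% ± 0.317 and stem-lineage-specific genes at 48.2% ± 9.42. For the mesangial fraction these values argue against a need for loss over 12 days, though they come from other chips. The endothelial-specific genes stood at 68.3% ± 32.4 in the endothelial fraction of the IM chip, so loss stays open there.

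The second pattern is the endothelial RNA in the mesangial fraction of the IM chip. RNA of endothelial cells has what it needs there: 100% of the 48 endothelial-specific genes lay within 2-fold of their median share of the level in the endothelial fraction, which was 29.5% (15.5 to 57.1). This test replaced an earlier one whose outcome was fixed. Its shares are of means over 4 libraries, between which the set ran from 5.56% to 48.2% of endothelial plate level in the mesangial fraction. An exchange of endothelial and mesangial libraries is argued against, since 0 of the 4 endothelial libraries had a stem-lineage level inside the range of the mesangial libraries (at most 25.8% against at least 41.2%), and the endothelial-specific genes were higher in the endothelial than in the mesangial fraction of the same chip in 4 of the 4 chips that the labels number. Between chips the ranges of these genes overlapped, with 1 mesangial library inside the endothelial range and 2 endothelial libraries inside the mesangial range. Endothelial cells left behind when the bottom channel was lysed after TrypLE are a possible source, and no biological explanation was tested.

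The third pattern is the podocyte fraction of TGC against BGC, with 386 genes lower and 34 higher in TGC. Depth is argued against, since 89.2% of the count remained in number after thinning all libraries to equal totals. Genes lower in TGC were poorer in GC, with a probability of 0.253 of exceeding another tested gene, and longer (0.727), with medians of 41.3% against 48.5% GC and 6054 against 3502 nucleotides, but a trend with length and GC as the whole cause is argued against, since 95.2% of the count (400 genes, with 294 of the 386 shared) stood after that trend was taken out of each library. A difference between the 2 sets of chips stays open, since 98.4% of the lower genes tested in the endothelial fraction (375 of 381) were lower there too, against 40.6% of other genes, and cannot be told apart from the mesangial cells, because each set of chips is 1 group and the endothelial fraction holds stem-lineage RNA levels. Chance cannot be excluded for this comparison: in a fit of these 8 libraries the real groups passed 538 genes and 2 of 35 splits, the real one included, passed as many, the highest other 1234, for a cause that was not tested.

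In the endothelial fraction, TGC against BGC passed 25 genes in a fit of the 8 libraries and another split passed 26, so that chance cannot be excluded (2 of 35 splits). For the difference of that change between fractions the real split passed 0 genes by edgeR (466 at an unadjusted p below 0.05, and 0 by DESeq2). The highest other split passed 7. Against a real count of 0 all 35 splits pass as many by construction, so these splits decide nothing. For every other comparison of 2 groups in the report, fitted on its 8 libraries, the real split was the 1 of 35 with a count as large. An arbitrary grouping of these libraries is therefore argued against for each comparison taken alone, 1 of 35 being the smallest share possible. If the libraries of a group are technical repeats, the splits do not test chance between cultures or chips. The highest other split passed 5 genes for the mesangial fraction of TGC against the IM chip (real count 3121) and 0 for the rest. The real counts of the rest were 7955, 7904, 4501 and 5223 for endothelial TGC and BGC against plate, TGC against IM chip and IM chip against plate, 7144, 6498, 6608, 4631 and 5657 for podocyte TGC and BGC against plate, podocyte against IM plate, IM cells on the IM chip against plate and podocyte TGC against those, and 7921 and 5760 for mesangial TGC and IM chip against plate.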

How the results depend on the processing

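The alternatives were chosen before the data were examined, except the fit without the IM chip group, thinning to equal totals, leaving out genes higher in the podocyte fraction, the length and GC trend, and all settings of the comparisons between fractions of TGC and between plates of different cell types. The counts of the comparisons with plates, IM plates or the IM chip, of fractions of TGC, of plates of different cell types and of the TGC to plate changes between cell types stayed within 1.5 times under RLE scaling, no low-count filter, DESeq2, a fit of the 2 groups, leaving out genes of other cell types and leaving out each library in turn, wherever each was run. Single-library omissions gave 7707 to 8006 (endothelial TGC against plate, 8042), 7375 to 7549 (BGC against plate, 7719), 5086 to 5636 (TGC against IM chip, 5635), 4874 to 5712 (IM chip against plate, 5550), 6996 to 7217 (podocyte TGC against plate, 7369), 6556 to 6692 (BGC against plate, 6871), 6221 to 6376 (podocyte against IM plate, 6594), 4457 to 4838 (IM chip against IM plate, 4970), 5825 to 6121 (podocyte TGC against IM cells on the IM chip, 6253), 6601 to 6984 (mesangial TGC against plate, 7071), 3547 to 4752 (TGC against IM chip, 4138) and 5732 to 6687 (IM chip against plate, 6303). They gave 996 to 1769 for the endothelial and 1452 to 3054 for the mesangial against the podocyte fraction of TGC, 8472 to 8688 and 7798 to 8057 for the plates, and 6937 to 7302, 6042 to 6509 and 6448 to 6962 for the differences between cell types. A replicate block gave 5259, 6419, 4836 and 5430 genes for endothelial IM chip, podocyte plate against IM plate, IM cells and mesangial IM chip, and 1544, 2083, 8436 and 7884 for the comparisons added later. Requiring a 2-fold change as well left fewer genes by construction: 5047, 4849, 2979 and 2792 for the endothelial comparisons in the order above, 3489, 3198, 2923, 1565 and 2465 for podocyte and IM cells, 4285, 1999 and 3587 for mesangial cells and 34 for podocyte TGC against BGC.

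For endothelial TGC against BGC the count of 0 by edgeR (1373 genes at an unadjusted p below 0.05) became 130 by DESeq2, 25 in a fit of the 2 groups, 103 without the IM chip group, 28 after thinning and 18 without TGC replicate 10, and ranged from 0 to 18 over single-library omissions; the cause was not tested. For podocyte TGC against BGC the count of 420 ranged from 193 to 733: 226, 205, 733 and 193 without TGC replicates 9, 10, 11 and 12, and 639, 198 and 214 without BGC replicates 21, 22 and 23; the cause was not tested. The share of genes higher in TGC was 8.1%, against 9.51% by DESeq2 and 6.77% with RLE scaling. The difference of that change between cell types went from 0 (466 unadjusted; 0 by DESeq2) to 1 with no low-count filter and to 1 without endothelial TGC replicate 9 or podocyte TGC replicate 9, within 0 to 1 over all single-library omissions; the cause was not tested.

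Of 2930 pairs of a named gene and a setting, 2874 kept their direction and side of the threshold, 49 no longer passed, 7 newly passed and 0 reversed, and 209 of 219 genes in a comparison were the same under every setting. Without endothelial IM chip replicate 4, PECAM1 against plate was at 0.52 and no longer passed, and CDH5 was at -0.66 and passed. For podocyte TGC against BGC, PFAS, MGME1, EPHA2, MLST8, CYB5D2, RBM43 and FLT1 missed the threshold under at least 1 setting, such as 0.88, 0.78, 0.73, 0.59, 0.58, -1.08 and -0.29 without TGC replicate 9; the cause was not tested. ACTA2 in mesangial TGC against the IM chip passed with RLE scaling (0.43), DESeq2 (0.44) and no low-count filter (0.43), and without mesangial TGC replicate 10 (0.50) or IM chip replicates 1 (0.54) and 2 (0.50). Depth sets the floor of 0.151 to 0.246 CPM, under which a gene with 0 counts cannot be told from absent.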

Other observations

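The comparisons between fractions of TGC and the genes named in this part were chosen after their values were seen. The endothelial fraction of the tri-culture chip (TGC) differed from the podocyte fraction at 1370 genes, where the plates of the 2 cell types differed at 8626 (edgeR, adjusted p below 0.05, n = 4 libraries per group). ESM1, a secreted product of sprouting endothelium, stood at 22.8 ± 13.1 and 0.0604 ± 0.121 CPM in the endothelial and podocyte fractions, and PECAM1 at 20.6 ± 6.22 and 0.437 ± 0.319 CPM (5.54 ± 0.43). The collagenase MMP1 and the granule proteoglycan SRGN were higher in the endothelial fraction by 6.78 ± 0.54 and 6.20 ± 0.6. The contractile genes TAGLN and ACTA2 were higher there by 2.00 ± 0.14 and 1.61 ± 0.16, and HHIP, an inhibitor of hedgehog signalling, by 3.29 ± 0.27. The calcium-binding protein SCGN, at 3.10 ± 1.33 and 51.0 ± 1.3 CPM, was lower by -4.03 ± 0.23, SAA1 by -3.16 ± 0.17 and PODXL by -1.55 ± 0.13. COL1A1 and SYNPO were higher in the endothelial fraction by 0.89 ± 0.13 and 0.93 ± 0.14, and KDR was lower by -0.70 ± 0.15. SPON2, DLK1 and PDGFRB differed by -0.22 ± 0.15, -0.24 ± 0.15 and -0.02 ± 0.13 and did not pass, with adjusted p = 0.41, 0.36 and 0.95. In plates the stem-lineage factor PITX1 was at 0 CPM in endothelial cells and 1440 ± 181 CPM in podocytes, and SRGN at 2060 ± 61.5 and 0 CPM. Of 35 splits of the 8 libraries of the 2 fractions or of the 2 plates, the real one included, no other passed any gene. This argues against an arbitrary grouping of these libraries for 1370 and for 8626, within the limits of such splits given above.

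The mesangial fraction of TGC differed from the podocyte fraction at 2093 genes, against 8014 between the plates. MMP1 was higher in the mesangial fraction by 5.19 ± 0.63, HHIP by 2.78 ± 0.27, TAGLN by 1.53 ± 0.14, ACTA2 by 1.25 ± 0.12 and PECAM1 by 4.11 ± 0.59. HHIP and PECAM1 belong to the endothelial-specific set, with HHIP at 1370 CPM in endothelial and 2.72 CPM in mesangial plates, so neither marks mesangial cells here. That set stood at 0.926% of plate level in the mesangial fraction and at 0.0728% in the podocyte fraction of TGC. PODXL was lower by -1.27 ± 0.1, SAA1 by -1.27 ± 0.17 and GPR155, a cholesterol sensor of the lysosome, by -2.25 ± 0.15. SPON2 was lower by -0.63 ± 0.1 and KDR by -0.44 ± 0.1, and SYNPO was higher by 0.49 ± 0.13. COL1A1, DLK1 and PDGFRB differed by 0.12 ± 0.08, 0.19 ± 0.11 and -0.05 ± 0.12 and did not pass (adjusted p = 0.33, 0.26 and 0.8). Oxidative phosphorylation genes were higher in 18 of 28 and cell cycle genes in 12 of 29, with 0 lower in either list, and cholesterol synthesis genes were higher in 9 of 18 and lower in 2. No list test was run for this comparison, so these counts do not show that the lists stand out from other genes. In plates PDGFRB was at 168 ± 12.4 CPM in mesangial cells and 43.1 ± 10.1 CPM in podocytes (1.85 ± 0.11), and TAGLN was lower by -7.07 ± 0.11 and COL1A1 by -3.02 ± 0.08 in mesangial cells. Other splits of these libraries passed 0 genes, which argues against an arbitrary grouping for 2093 and for 8014 within the same limits.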
